A study of Homo sapiens with 16 samples.

How the data were processed

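Gene expression in HBL-1 cells was measured on 16 dual-colour Agilent arrays with 45015 features each, of which 1639 were control features and the rest held 41000 probes. Control RNA was labelled with Cy3 and treated RNA with Cy5 on every array, without a dye swap, so a dye effect of a probe stays in each group's ratio. It cancels between groups only where it is equal on their arrays. Per the labels, 2 µg of RNA was labelled for the MLN120B arrays and 1 µg for the others. For the 4 MYD88 shRNA and 4 JAK inhibitor I arrays the deposited scanner files gave signals and local backgrounds as intensity. Per the file headers these came from Agilent Feature Extraction 10.1.1.1, with background subtraction and dye normalization by LOWESS for the processed signals. The scanner files also held log10 ratios of the processed signals, and other columns, deposited as flags of 0 or 1 for spots well above background, outlier spots and saturated spots. For all 16 arrays, the 8 MLN120B arrays among them, the deposited value table held the log10 ratio of Cy5 to Cy3 processed signals. On the 8 arrays with both sources all 45015 features of each array lay within 0.00051 log10 of the scanner's ratio, so the scale and direction of the table were checked there and taken over for the MLN120B arrays, where they could not be checked. Ratios were converted to log2.

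Median Cy3 intensity was 1.62 to 1.9 times and median Cy5 intensity 1.84 to 2.84 times the local background; 86 to 158 spots per array were outliers and 0 were saturated. Outlier spots were left out and spots of a probe averaged. Probes were named through the RefSeq accession in the scanner files (23680), a current symbol (2802), an older symbol (1128) or the files' own name (13390), which gave 30499 gene names, 7782 of them with more than 1 probe; each gene was represented by its brightest probe. Gene names came from GRCh38.p14 annotation and probe positions from the files, in hg18. A probe was tested if it was well above background in at least 1 channel on at least 2 arrays of the group (scanner files), or on at least 4 of the 8 scanner arrays with values on at least 75 percent of the arrays of each group (value table).

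For the MYD88 shRNA and JAK inhibitor I arrays, mean signals were background corrected with normexp (offset 50) and normalized by loess within arrays in limma 3.58.1 (R 4.3.3, statmod 1.5.0, data.table version 1.17.8). For the MLN120B arrays the log2 of the deposited ratios was used as it is. The mean ratio of each group was tested against 0 with limma's moderated test, two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Differences between groups used a single model with 3 group means, fitted to all 16 arrays of the value table. Differences between the shRNAs and between 24 h and 48 h came from an additive limma fit on the 4 MYD88 shRNA arrays, and time slopes were fitted on log2 hours. The 23 gene lists were tested with camera at a preset correlation of 0.01, adjusted over all lists and the 3 treatments, with camera at an estimated correlation and fry beside it. Overlaps of lower genes came from 1 limma fit per pair of treatments on the value table, with a spread shared by both, and were tested with Fisher's exact test, one-sided. The MYD88 shRNA and JAK inhibitor means come from the scanner files and the MLN120B means from the value table, so these differ in source. Differences between treatments and overlaps come from the value table alone.

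The lists were NF-κB targets, JAK-STAT targets, type I interferon response, cytokines and chemokines, Toll-like receptor pathway, B cell receptor pathway, ABC lymphoma genes, germinal centre B cell genes, unfolded protein response, G2/M cell cycle, DNA replication, MYC and ribosome biogenesis, integrated stress response, p53 targets, apoptosis regulators, sterol synthesis, glycolysis and hypoxia, MHC class II, immediate early genes, oxidative phosphorylation, and markers of T and NK cells, myeloid cells and fibroblasts. Some genes stand in more than 1 list, BATF, IRF4, BCL3 and TNF among them. The lists, comparisons, tests and most alternatives were chosen before the data were examined. The genes named were MYD88, IL6 and IL10 in each comparison; the 10 lowest and 10 highest with a symbol among genes past the threshold and on the same side of 0 on every array of the group; up to 4 members of each list past the threshold with the largest change, or the 2 with the smallest p where 0 passed; the 5 lowest and 5 highest of each difference; and the 10 lowest sums of each overlap.

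The fits were tested on simulated normal log2 ratios drawn with each gene's moderated residual spread, 200 genes of them changed. At a change of 1 log2, 100 percent were recovered for MYD88 shRNA, 100 percent for JAK inhibitor I and 97 percent for MLN120B. For the difference between MYD88 shRNA and MLN120B it was 83.6 percent. At 0.585 log2 these shares were 100, 94, 89.6 and 49.3 percent. Over all sizes, of 229, 212, 204 and 160 calls 29, 16, 13 and 7 were false. For each treatment, though not for the difference, that share exceeded the adjusted p threshold. These draws cannot give the recovery on the real arrays. There SOCS3 (-1.74, adjusted p = 0.0519 in limma) and LMO2 (-1.03, adjusted p = 0.0966) did not pass under the JAK inhibitor. Alternatives tried were no background correction, the scanner's processed signals, median centring, the value table, filters on dim probes, the mean over probes, a shared spread, an intensity trend, time and shRNA terms, a minimum change of 1.5-fold, each run of IDs, matched times, and leaving out each array. Further alternatives were chosen after seeing the data: leaving out the JAK inhibitor I 4 h and MLN120B 16 h arrays, the value table and single runs for the lists, and list tests of the differences between treatments. No arrays were left out of the comparisons. RNA sequencing named in the study's description was not used here. A few genes that the rules above select are not reported here, though every fit and count includes them.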

Results

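Gene expression was measured in HBL-1 cells, an established line of the activated B-cell-like (ABC) form of diffuse large B-cell lymphoma, on 16 dual-colour Agilent arrays. Each array compared RNA of treated cells, labelled with Cy5, with RNA of control cells, labelled with Cy3. MYD88 shRNA, induced in cells selected for the construct, was measured on 4 arrays: shMYD88-7 and shMYD88-4, each at 24 h and 48 h, against uninduced cells. JAK inhibitor I at 5 µM was measured on 4 arrays at 2, 4, 6 and 8 h, against the solvent DMSO. MLN120B, an inhibitor of IκB kinase beta, at 25 µM was measured on 8 arrays at 2, 3, 4, 6, 8, 12, 16 and 24 h, against untreated cells. The sample IDs put the MLN120B arrays at 3, 6, 12 and 24 h in the run of the MYD88 shRNA arrays, and those at 2, 4, 8 and 16 h in another. On the 8 MYD88 shRNA and JAK inhibitor arrays the median intensity was 189 to 229 in Cy3 and 237 to 386 in Cy5, and 67 to 71.5% of probes in Cy3 and 74.1 to 80% in Cy5 lay well above background. For the MLN120B arrays only ratios were used, and their depth was not analysed here. The number of arrays limits the precision of every value. Nothing in the labels says that the arrays of a group came from separate cultures, so each p-value measures at most the spread between these samples. Each gene's spread also draws on that of other genes, as limma moderates it. Values are log2 ratios of treated to control cells, given as the mean ± SD over arrays with the adjusted p of limma.

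The MYD88 shRNA arrays address which transcripts depend on MYD88, the adaptor that carries signals from Toll-like and interleukin-1 receptors. MYD88 itself fell to -1.34 ± 0.24 (SD, n = 4; adjusted p = 7.35e-05), from -1.66 with shMYD88-7 at 24 h to -1.13 with shMYD88-4 at 48 h (probe A_23_P362659, chromosome 3, 38158936 to 38158995 in hg18). SOCS3, the feedback inhibitor of JAK-STAT signalling, fell to -1.05 ± 0.19 (adjusted p = 8.27e-05; probe A_23_P207058, chromosome 17, 73864722 to 73864781). ABTB2 fell to -0.98 ± 0.11, the motor protein gene MYO7A to -0.92 ± 0.03 and the metalloprotease gene ADAM8 to -0.91 ± 0.18. LRRC32, whose product tethers latent TGF-beta, fell to -0.90 ± 0.29, and the other genes at the lower end were HLF (-0.89 ± 0.14), RNF183 (-0.85 ± 0.33), IFI44L (-0.84 ± 0.15) and LAT2 (-0.83 ± 0.37). Of the 10 genes at the upper end, most code for ribosomal proteins, among them RPL23 (1.15 ± 0.08), RPS27 (1.12 ± 0.06), RPS28 (1.03 ± 0.07), RPL41 (0.95 ± 0.07) and RPL35 (0.92 ± 0.04). RPS2 was a further ribosomal protein gene among them at 0.95 ± 0.09, with 1 of its 5 other probes on the same side of 0. The elongation factor gene EEF1A1 (1.02 ± 0.09), the histone gene H3-3A (1.00 ± 0.13) and OAZ1 (1.00 ± 0.11) stood there too, and 59 other genes as bright as the brightest 52 ribosomal protein genes had a median of 0.56 against their 0.70. In all, 5805 of 23361 tested genes passed, 3379 higher and 2426 lower. The test against 0 leaves out the spread of the control cells, and without a dye swap a dye effect of a probe stays in the ratio. No array here held another shRNA, so effects of induction and of shRNA expression cannot be told apart from MYD88 loss. Without the shMYD88-4 24 h array 2905 genes passed and without the shMYD88-4 48 h array 3821, while an added minimum change of 1.5-fold left 161. Median centring gave 12464 higher and 5857 lower genes, the processed signals 3393 genes and the deposited ratios 3396.

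With loess the NF-κB, JAK-STAT, interferon, cytokine and ABC lymphoma lists were lower under the MYD88 shRNAs, though none passed with an estimated correlation. Fry tests a list against 0 rather than against the other genes. By fry the NF-κB (adjusted p = 0.0255), JAK-STAT (0.033), cytokine (0.0239) and ABC (0.0239) lists passed, and the interferon list (0.0539) did not. Of 33 tested NF-κB targets 23 fell and 1 rose (25 and 1 adjusted over the list alone), among them the chemokine gene CCL4 (-0.77 ± 0.04), the AP-1 family gene BATF (-0.73 ± 0.06), the nuclear IκB gene NFKBIZ (-0.73 ± 0.18) and the cyclin D2 gene CCND2 (-0.66 ± 0.18). The list had a median of -0.26, and with median centring 13 members were higher and 10 lower (camera adjusted p = 2.64e-11; adjusted p = 0.385 with an estimated correlation). Of 21 JAK-STAT targets 11 fell and 0 rose (12 and 0 adjusted over the list alone), among them the kinase gene PIM2 (-0.44 ± 0.15) and BCL3 (-0.44 ± 0.14). The median was -0.22 (adjusted p = 1.68e-05; adjusted p = 0.385 with an estimated correlation). Of 37 genes of the type I interferon response 22 fell and 2 rose (24 and 2 adjusted over the list alone), among them IFIT3 (-0.64 ± 0.19), IFIT1 (-0.61 ± 0.21) and IFI44 (-0.56 ± 0.12). Their median was -0.25, and 0.03 with median centring in place of loess (adjusted p = 5.9e-10; adjusted p = 0.458 with an estimated correlation). Of 17 cytokine and chemokine genes 8 fell and 0 rose (10 and 0 adjusted over the list alone). The list median was -0.20 (adjusted p = 1.6e-05; adjusted p = 0.385 with an estimated correlation). IL10 fell to -0.49 ± 0.20 (adjusted p = 0.00277), IL6 to -0.34 ± 0.13 (adjusted p = 0.00332), EBI3 to -0.45 ± 0.18 and CCL3 to -0.45 ± 0.29. Of 20 genes typical of ABC lymphoma 9 fell and 3 rose, 9 and 3 adjusted over the list alone as well, with CYB5R2 at -0.59 ± 0.15 and SH3BP5 at 0.50 ± 0.12. Their median was -0.09, and 0.17 with median centring (adjusted p = 0.00232; adjusted p = 0.385 with an estimated correlation). Median centring moved the median of all genes to 0.15, and relative to it the lists lay at -0.16 (NF-κB), -0.22 (JAK-STAT), -0.12 (interferon), -0.30 (cytokines) and 0.01 (ABC).

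The lists of DNA replication, integrated stress response, sterol synthesis, G2/M phase and MYC genes were lower as well with loess, while MHC class II was higher. By fry DNA replication (adjusted p = 0.0497) and sterol synthesis (0.0239) passed. The integrated stress response (0.241), G2/M (0.117), MYC (0.405) and MHC class II (0.0658) lists did not pass fry. Of 24 DNA replication genes 16 fell and 1 rose (19 and 1 adjusted over the list alone). The licensing factor gene CDT1 lay at -0.47 ± 0.08, the licensing factor gene CDC6 at -0.38 ± 0.10, UHRF1 at -0.42 ± 0.18 and CDC45 at -0.37 ± 0.11. Their median was -0.20, and 0.12 with median centring (adjusted p = 7.31e-09; adjusted p = 0.458 with an estimated correlation). Of 22 genes of the integrated stress response 8 fell and 0 rose (16 and 0 adjusted over the list alone), among them STC2 (-0.59 ± 0.57), the transcription factor gene ATF5 (-0.53 ± 0.40), SLC3A2 (-0.48 ± 0.28) and the asparagine synthetase gene ASNS (-0.43 ± 0.41). Their median was -0.45 (adjusted p = 1.36e-06; adjusted p = 0.652 with an estimated correlation), and the mean of the list was -0.07 and -0.08 on the 24 h arrays and -0.56 and -1.25 on the 48 h arrays. Of 19 sterol synthesis genes 9 fell and 0 rose (13 and 1 adjusted over the list alone), among them INSIG1 (-0.25 ± 0.08), MVD (-0.22 ± 0.12) and DHCR7 (-0.22 ± 0.10). The median was -0.12, and 0.22 with median centring (adjusted p = 1.16e-05; adjusted p = 0.385 with an estimated correlation). Of 22 genes of the G2/M phase 6 fell and 0 rose (8 and 0 adjusted over the list alone), among them UBE2C (-0.26 ± 0.09), CDK1 (-0.24 ± 0.04), KIF11 (-0.22 ± 0.06) and PLK1 (-0.24 ± 0.09, with its other probe on the opposite side of 0). Their median was -0.08, and 0.25 with median centring (adjusted p = 0.00139; adjusted p = 0.654 with an estimated correlation). Of 24 genes of MYC and ribosome biogenesis 8 fell and 3 rose (11 and 3 adjusted over the list alone). RRS1 lay at -0.37 ± 0.17, NIP7 at -0.33 ± 0.04, MRTO4 at -0.33 ± 0.12 and NPM1 at 0.63 ± 0.08, with 1 of 5 other NPM1 probes on the same side of 0. Their median was -0.12, and 0.31 with median centring (adjusted p = 0.0152; adjusted p = 0.694 with an estimated correlation). All 12 MHC class II genes lay above 0 adjusted over the list alone and 9 over all genes, with HLA-DRA at 0.46 ± 0.27, HLA-DPB1 at 0.44 ± 0.26, HLA-DOA at 0.41 ± 0.17 and HLA-DMA at 0.40 ± 0.18. Their median was 0.28, and 0.60 with median centring (adjusted p = 1.6e-05; adjusted p = 0.518 with an estimated correlation). Relative to the median of all genes under median centring, the lists lay at -0.03 (DNA replication), -0.28 (integrated stress response), 0.07 (sterol synthesis), 0.09 (G2/M), 0.16 (MYC) and 0.44 (MHC class II). With median centring UBE2C lay at 0.17, CDK1 at 0.13, PLK1 at 0.26, KIF11 at 0.08, CDC45 at 0.12, NIP7 at 0.04, MRTO4 at 0.05, ASNS at 0.10, INSIG1 at 0.05, MVD at 0.01 and DHCR7 at 0.19.

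The remaining 12 lists did not pass camera under the MYD88 shRNAs, though by fry the germinal centre and myeloid lists were higher (adjusted p = 0.0239 each). B cell receptor genes had 11 higher and 3 lower of 19 (11 and 5 adjusted over the list alone; list adjusted p = 0.0589). The receptor component CD79A lay at 0.73 ± 0.24, PLCG2 at 0.39 ± 0.04 and CD72 at 0.34 ± 0.17. Toll-like receptor genes had 8 higher and 3 lower of 24 (8 and 4 adjusted over the list alone; adjusted p = 0.626). CD180 lay at 0.32 ± 0.23, TLR9 at 0.30 ± 0.10 and TLR1 at 0.29 ± 0.07. Germinal centre genes had 6 higher and 0 lower of 15 (7 and 1 adjusted over the list alone; adjusted p = 0.217). STAP1 lay at 0.33 ± 0.13, ITPKB at 0.32 ± 0.14, IRAG2 at 0.25 ± 0.12 and RGS13 at 0.20 ± 0.15. Immediate early genes had 6 higher and 3 lower of 24 (8 and 4 adjusted over the list alone; adjusted p = 0.457). EGR1 lay at 0.89 ± 0.31, EGR2 at 0.80 ± 0.48, EGR3 at 0.56 ± 0.54 and NR4A1 at 0.64 ± 0.16, whose other probe lay on the opposite side of 0. Targets of p53 had 7 higher and 3 lower of 22 (the same counts adjusted over the list alone; adjusted p = 0.456). BTG2 lay at 0.60 ± 0.30, TP53INP1 at 0.40 ± 0.11, PLK3 at -0.52 ± 0.21 and BAX at -0.36 ± 0.25. Apoptosis regulators had 5 higher and 7 lower of 20 (5 and 8 adjusted over the list alone; adjusted p = 0.429). PMAIP1 lay at -0.66 ± 0.30, CFLAR at -0.56 ± 0.14 and BIK at 0.40 ± 0.25; their median was 0.01, while their mean of -0.05 and the test pointed down. Oxidative phosphorylation had 5 higher and 0 lower of 20 (9 and 2 adjusted over the list alone; adjusted p = 0.0652). ATP5F1A lay at 0.40 ± 0.05, COX4I1 at 0.36 ± 0.07, UQCRQ at 0.33 ± 0.06 and ATP5PO at 0.32 ± 0.07. Glycolysis and hypoxia had 2 higher and 5 lower of 20 (3 and 8 adjusted over the list alone; adjusted p = 0.0842). ADM lay at 0.45 ± 0.14, LDHA at -0.27 ± 0.07, HK2 at -0.26 ± 0.18 and PFKFB4 at -0.18 ± 0.12, the last 3 at 0.29, 0.12 and 9e-04 with median centring. The unfolded protein response had 3 higher and 1 lower of 16 (4 and 1 adjusted over the list alone; adjusted p = 0.975). DNAJB9 lay at 0.20 ± 0.13, MANF at 0.17 ± 0.06 (-0.02 on the deposited ratios), SEL1L at 0.15 ± 0.09 and PDIA4 at -0.17 ± 0.06 (0.16 with median centring). Among markers of cells that a pure culture should lack, 2 of 10 T and NK cell genes rose (list adjusted p = 0.537). LCK lay at 0.69 ± 0.16 and GZMA at 0.16 ± 0.10, and -0.24 with median centring. Of 9 myeloid markers 2 rose (3 adjusted over the list alone; list adjusted p = 0.55), ITGAM at 0.21 ± 0.17 and CD68 at 0.15 ± 0.10 (-0.0073 with median centring), and of 8 fibroblast markers COL5A1 rose, at 0.28 ± 0.23 (list adjusted p = 0.545).

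**Figure D1:**
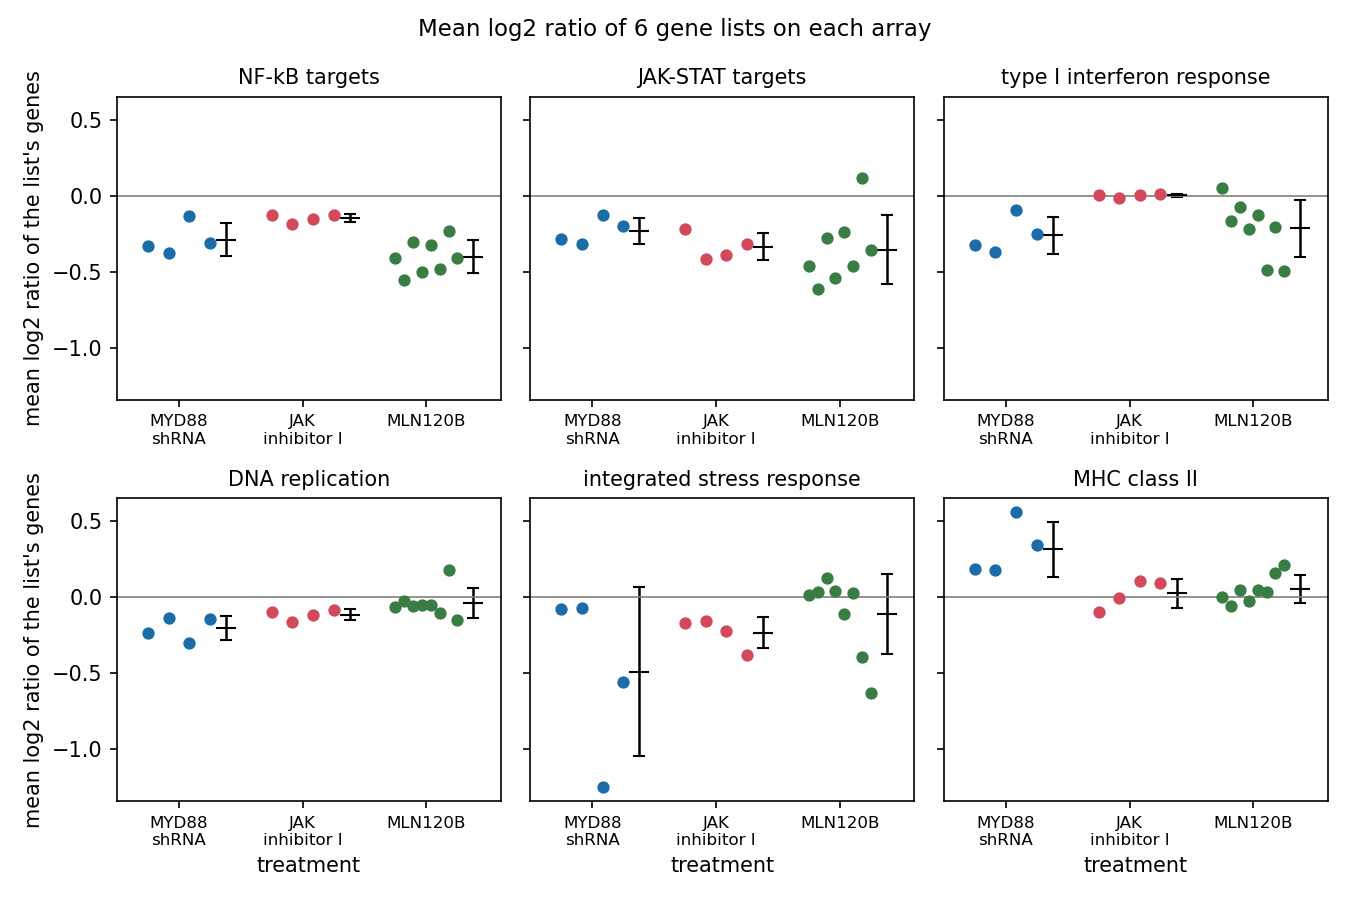
Mean log2 ratio of treated to control cells over the genes of 6 lists (y axis, log2) on each array, by treatment (x axis); points are arrays in order of time, bars the mean ± SD over 4 MYD88 shRNA, 4 JAK inhibitor I and 8 MLN120B arrays. Values of the MYD88 shRNA and JAK inhibitor I arrays come from the scanner files and those of MLN120B from the deposited ratios. NF-κB targets lay below 0 on every array shown, and MHC class II lay above 0 on the 4 MYD88 shRNA arrays. With median centring the median of the NF-κB list under the JAK inhibitor lay at 0.32.

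The JAK inhibitor arrays address which transcripts depend on JAK kinase signalling. The lowest genes that passed were the co-chaperone gene DNAJC7 (-0.88 ± 0.17, n = 4, adjusted p = 0.0358), ANP32D (-0.87 ± 0.17), TMEM184B (-0.80 ± 0.11, n = 3), DLST (-0.75 ± 0.17) and PFDN6 (-0.69 ± 0.16). FBXO34 (-0.62 ± 0.09), RGS16, a regulator of G protein signalling (-0.58 ± 0.10), CCDC86 (-0.55 ± 0.09) and the adhesion molecule gene ICAM1 (-0.54 ± 0.09) fell as well, and CEBPB fell to -0.56 ± 0.11 while its other probe lay on the opposite side of 0. SOCS3 lay at -1.74 ± 0.51 and MYC at -0.95 ± 0.26, both with an adjusted p of 0.0519, and BATF at -0.73 ± 0.32 (adjusted p = 0.075). IL10 lay at -0.38 ± 0.24 (adjusted p = 0.128), IL6 at -0.09 ± 0.06 (adjusted p = 0.297) and MYD88 at 0.04 ± 0.08 (adjusted p = 0.642). The highest genes were SPPL2B (1.1 ± 0.24), PRR7 (0.99 ± 0.08, adjusted p = 0.00835), SOX3 (0.96 ± 0.03), GPR153 (0.93 ± 0.12), the apoptosis gene HRK (0.90 ± 0.04), PHOX2A (0.89 ± 0.12), COX6A2 (0.80 ± 0.19), the prion protein gene PRNP (0.68 ± 0.09), CDH24 (0.66 ± 0.08) and TSPAN10 (0.65 ± 0.06). The other probes of PRR7 (0 of 2), HRK (0 of 1) and PRNP (0 of 1) did not lie on the same side of 0. In all, 55 of 24364 tested genes passed, 40 higher and 15 lower, and 4838 had an unadjusted p under 0.05. The count was 0 without the 2 h, the 6 h or the 8 h array, 565 without the 4 h array, 0 with the mean over all probes of a gene and 0 with log2 time as a term. Median centring gave 4376 higher and 341 lower genes and moved the median of all genes to 0.15.

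Across the 8 MLN120B arrays, the mean of those 10 highest genes followed the log2 ratio of 14 control spots at the corners of the array with a Pearson r of 0.953 (exact permutation p = 0.000372) and a Spearman rho of 0.976 (exact permutation p = 0.000397, adjusted p = 0.000397 for both of 2 relations). Without the 2 arrays farthest from the median r was 0.939, and within the runs of IDs r was 0.989 (2, 4, 8 and 16 h) and 0.999 (3, 6, 12 and 24 h), each with the smallest exact permutation p that 4 arrays allow, 0.0417. The mean of the 10 genes was 0.87 ± 0.08 (n = 4) on the JAK inhibitor arrays, 0.30 ± 0.24 (n = 4) on the MYD88 shRNA arrays and -0.23 ± 0.78 (n = 8) on the MLN120B arrays, and the corner spots lay at 0.93 ± 0.60, 0.27 ± 0.28 and -0.15 ± 0.60.

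**Figure D2:**
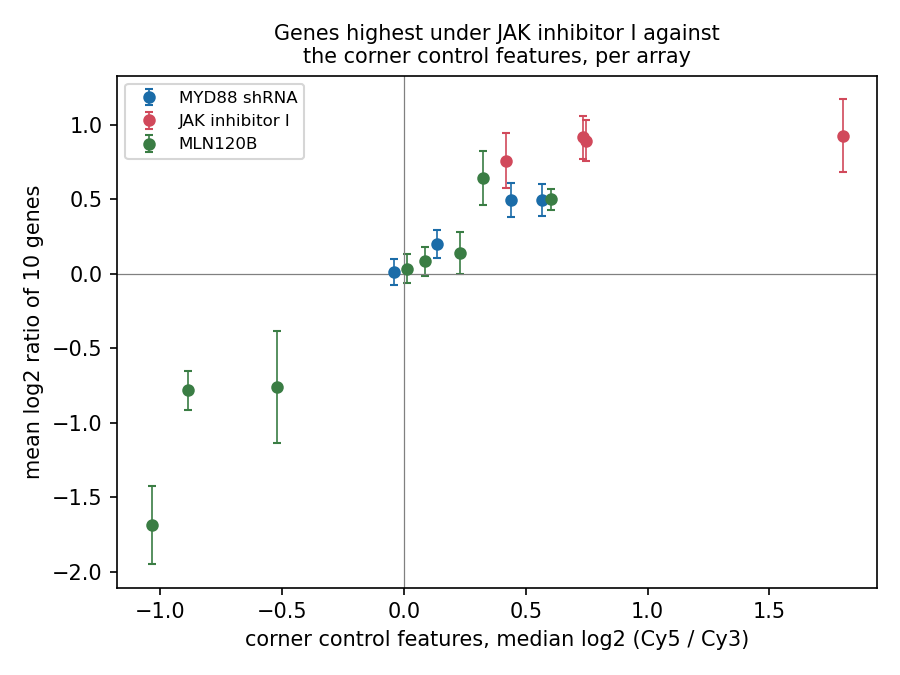
Mean log2 ratio of the 10 genes highest under JAK inhibitor I (y axis, log2, error bars the SD over the 10 genes) against the median log2 ratio of Cy5 to Cy3 of the corner control spots (x axis, log2); each point is 1 of 16 arrays. The lowest array on both axes is MLN120B at 2 h, at -1.69 and -1.04, and the farthest to the right is JAK inhibitor I at 4 h, at 1.80.

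With loess 8 lists were lower under the JAK inhibitor and 1 higher, while with median centring 11 passed and all pointed up. By fry NF-κB targets (adjusted p = 0.00121), JAK-STAT targets and DNA replication (0.0239 each) were lower, and no other list passed. Median centring moved the median of all genes to 0.15, against which list medians under it are to be read. The JAK-STAT (0.02) and immediate early (0.03) lists lay below that value. The other lower lists lay above it. Of 21 JAK-STAT targets 0 passed over all genes and 10 were lower adjusted over the list alone, with SOCS3 (above) and JAK3 (-0.39 ± 0.13, adjusted p = 0.0661) the closest. Their median was -0.17, and 0.02 with median centring (adjusted p = 1.13e-06; adjusted p = 0.385 with an estimated correlation). Of 22 integrated stress response genes CEBPB fell and 12 were lower adjusted over the list alone. The median was -0.22, and 0.18 with median centring (adjusted p = 7.44e-11; adjusted p = 0.385 with an estimated correlation). Of 34 NF-κB targets ICAM1 fell and 0 rose (11 lower and 2 higher adjusted over the list alone). The list median was -0.11, and 0.32 with median centring (adjusted p = 1.73e-05; adjusted p = 0.296 with an estimated correlation). Of 24 immediate early genes IER2 fell, to -0.51 ± 0.10, though it lay at 0.16 with median centring, and 10 were lower adjusted over the list alone. The median of that list was -0.06, and 0.03 with median centring (adjusted p = 0.000303; adjusted p = 0.385 with an estimated correlation). ABC lymphoma genes had 0 of 20 past the test, and 1 higher and 5 lower adjusted over the list alone, with IRF4, the plasmacytic transcription factor gene, at -0.51 ± 0.19 (adjusted p = 0.0654); their median was -0.12, and 0.36 with median centring (adjusted p = 0.00317; adjusted p = 0.385 with an estimated correlation). DNA replication had 0 of 24 past the test, and 1 higher and 5 lower adjusted over the list alone, with CDC45 at -0.42 ± 0.10 (adjusted p = 0.0582) and MCM4 at -0.30 ± 0.12 (adjusted p = 0.0886). Their median was -0.08, and 0.32 with median centring (adjusted p = 0.00374; adjusted p = 0.385 with an estimated correlation). The unfolded protein response had 0 of 16 past the test and 2 lower adjusted over the list alone, with XBP1 at -0.45 ± 0.09 (adjusted p = 0.0503) and PDIA4 at -0.23 ± 0.05; the median was -0.02, and 0.41 with median centring (list adjusted p = 0.0413; adjusted p = 0.385 with an estimated correlation). Sterol synthesis had 0 of 19 past the test and 1 lower adjusted over the list alone, with IDI1 at -0.42 ± 0.20 (n = 3); the median was -0.10, and 0.41 with median centring (list adjusted p = 0.028; adjusted p = 0.507 with an estimated correlation). Glycolysis and hypoxia was the list that passed upwards: of 20 genes ADM, which codes for adrenomedullin, rose to 0.63 ± 0.12 and 4 were higher and 1 lower adjusted over the list alone. Their median was 0.15 (adjusted p = 0.00761; adjusted p = 0.385 with an estimated correlation).

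Of the 14 lists that did not pass under the JAK inhibitor, the interferon list had 1 gene of 37 past the test, SAMD9L at 0.39 ± 0.04 (3 higher and 2 lower adjusted over the list alone). Its median was -0.02, its mean 0.0025, and the test pointed down (adjusted p = 0.626). Apoptosis regulators had HRK past the test (2 higher and 4 lower of 20 adjusted over the list alone; adjusted p = 0.0624), and MYC and ribosome biogenesis had 0 (1 higher and 5 lower of 24 adjusted over the list alone; adjusted p = 0.0596). NPM1 lay at 0.61 ± 0.20. Cytokines and chemokines had 0 of 19 past the test either way (adjusted p = 0.0783). IL12A lay at -0.30 ± 0.14. Toll-like receptor genes had 4 higher and 2 lower of 25 adjusted over the list alone (adjusted p = 0.78). CD180 lay at -0.50 ± 0.17 and MAP3K7 at 0.23 ± 0.03, and their median of 0.01 differed in sign from their mean of -0.01 and the test. B cell receptor genes had 2 higher and 2 lower of 19 adjusted over the list alone (adjusted p = 0.537). VAV1 lay at -0.36 ± 0.21 and CD72 at -0.29 ± 0.13. Germinal centre genes had 2 lower of 16 adjusted over the list alone (adjusted p = 0.671). LMO2 lay at -1.03 ± 0.57 and ELL3 at -0.44 ± 0.17, and a median of 0.02 against a mean of -0.07 and a test that pointed down. The G2/M list had 0 of 22 (adjusted p = 0.537). CDK1 lay at -0.21 ± 0.16 and CDC20 at 0.23 ± 0.18, and a median of 0.02 against a mean of -0.01 and a test that pointed down. Targets of p53 had 2 lower of 22 adjusted over the list alone (adjusted p = 0.626). ZMAT3 lay at -0.56 ± 0.22 and BAX at -0.55 ± 0.19. MHC class II had 0 of 12 (adjusted p = 0.692). CIITA lay at -0.21 ± 0.16 and HLA-DQB1 at 0.20 ± 0.15. Oxidative phosphorylation had 0 of 20 (adjusted p = 0.549). ATP5F1B lay at -0.14 ± 0.06, and 0.49 with median centring, and UQCRC2 at 0.11 ± 0.05. T and NK cell markers had 0 of 13 (adjusted p = 0.208). LCK lay at 0.31 ± 0.17 and CD4 at 0.16 ± 0.20. Myeloid markers had 1 higher and 1 lower of 10 adjusted over the list alone (adjusted p = 0.626). ITGAM lay at 0.18 ± 0.03 and CD33 at -0.22 ± 0.09, and fibroblast markers had 0 of 9 (adjusted p = 0.537). COL1A2 lay at -0.10 ± 0.02 and PDGFRB at 0.11 ± 0.07.

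The MLN120B arrays address which transcripts depend on IκB kinase beta, the kinase that releases NF-κB. TNFAIP2, a gene inducible by tumour necrosis factor, fell furthest, to -2.08 ± 0.71 (n = 8, adjusted p = 0.00107), and LRRC32 fell to -1.96 ± 0.62 (adjusted p = 0.000803). SOCS3 fell to -1.47 ± 0.63 (adjusted p = 0.00305), and ELF3 (-1.36 ± 0.71), FCRL4, an Fc receptor-like gene of B cells (-1.36 ± 0.59), RASGRP1 (-1.35 ± 0.50), KIF26B (-1.23 ± 0.34), NINJ1 (-1.21 ± 0.85), GPRC5B (-1.21 ± 0.28) and the cytokine gene IL26 (-1.20 ± 0.71) followed. MYD88 lay at -0.20 ± 0.24 (adjusted p = 0.138). Among the 10 highest genes were OR2W3 (3.00 ± 0.40, adjusted p = 8.27e-06), NECAB2 (2.81 ± 0.69), TPD52L3 (2.76 ± 0.61), GIMAP1 (2.71 ± 0.57), GABRA4 (2.63 ± 0.51), KLF17 (2.52 ± 1.15), NPTX2 (2.51 ± 0.61), MORN5 (2.45 ± 0.74) and LRRC2-AS1 (2.45 ± 0.81). These 10 were dim, with Cy3 above background on 0 to 4 of the 8 scanner arrays, and lay above 0 on 8 of 8 MYD88 shRNA and JAK inhibitor arrays too. In all, 3198 of 23873 tested genes passed, 2020 higher and 1178 lower, and 57 passed in the run of 2, 4, 8 and 16 h alone and 909 in the run of 3, 6, 12 and 24 h alone. Median centring gave 3243 higher and 793 lower genes, and no filter on dim probes 2421 higher and 4916 lower. Leaving out the 16 h array gave 5657 genes, the 4 h array 2064, the 8 h array 1750, the 6 h array 1873, the 12 h array 1695 and the 24 h array 2104.

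NF-κB targets were the list with the lowest median under MLN120B. Of 34 tested 21 fell and 0 rose (26 and 0 adjusted over the list alone). TNF lay at -1.12 ± 0.37, ICAM1 at -0.87 ± 0.21, the signalling adaptor gene TRAF1 at -0.81 ± 0.55 and CD40 at -0.78 ± 0.16; their median was -0.40 (adjusted p = 3.73e-15; adjusted p = 0.188 with an estimated correlation). Of 18 cytokine and chemokine genes 7 fell and 0 rose (9 and 0 adjusted over the list alone). IL10 lay at -1.05 ± 0.48 (adjusted p = 0.00416), EBI3 at -0.66 ± 0.45 and IL6 at -0.64 ± 0.38 (adjusted p = 0.0109). The median was -0.35 (list adjusted p = 1.36e-06; adjusted p = 0.188 with an estimated correlation). Of 21 JAK-STAT targets 9 fell and 0 rose (13 and 0 adjusted over the list alone). STAT5A lay at -1.02 ± 0.70, BATF at -0.73 ± 0.23 and the survival gene BCL2L1 at -0.62 ± 0.50. The list median was -0.30 (adjusted p = 1.36e-06; adjusted p = 0.385 with an estimated correlation). Of 37 interferon response genes 10 fell and 1 rose (11 and 1 adjusted over the list alone). IFIT3 lay at -0.90 ± 0.34, IFIT1 at -0.77 ± 0.63, IFI44L at -0.77 ± 0.53 and the RNA sensor gene IFIH1 at -0.67 ± 0.27. Their median was -0.19 (adjusted p = 5.13e-06; adjusted p = 0.503 with an estimated correlation). MYC and ribosome biogenesis had 7 lower and 0 higher of 24 (8 and 0 adjusted over the list alone). NOP16 lay at -0.40 ± 0.11, RRS1 at -0.38 ± 0.14, MYC at -0.34 ± 0.24 and MRTO4 at -0.32 ± 0.17. The median was -0.14 (adjusted p = 0.000303; adjusted p = 0.385 with an estimated correlation). ABC lymphoma genes had 5 lower and 1 higher of 20 (the same counts adjusted over the list alone). RAB29 lay at -0.63 ± 0.27, IRF4 at -0.45 ± 0.26 and SH3BP5 at 0.38 ± 0.18. The list median was -0.08 (adjusted p = 0.00691; adjusted p = 0.507 with an estimated correlation). Apoptosis regulators had 4 lower and 2 higher of 20 (6 and 3 adjusted over the list alone). BIRC3 lay at -0.59 ± 0.27, the caspase-8 regulator gene CFLAR at -0.36 ± 0.17 and BIK at 0.40 ± 0.21. Their median was -0.18 (adjusted p = 0.0361; adjusted p = 0.385 with an estimated correlation). The integrated stress response had 0 of 22 past the test, ATF5 at -0.33 ± 0.31 and CEBPG at -0.28 ± 0.26 the closest, and its median of -0.11 passed as a list (adjusted p = 0.0195; adjusted p = 0.69 with an estimated correlation). Its mean lay below 0 on only 3 of 8 arrays, at -0.11 (8 h), -0.39 (16 h) and -0.63 (24 h). On the others it lay between 0.02 and 0.13. The 8 lists kept the sign of their medians with median centring. By fry the NF-κB (adjusted p = 0.000723), cytokine (0.00121), JAK-STAT (0.0281), MYC (0.0255) and apoptosis (0.0239) lists passed. The interferon (0.0503), ABC (0.0965) and integrated stress response (0.307) lists did not pass fry.

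Of the 15 lists that did not pass under MLN120B, B cell receptor genes had 3 higher and 4 lower of 19 (7 and 5 adjusted over the list alone; adjusted p = 0.537). PLCG2 lay at 0.43 ± 0.27, VAV1 at -0.44 ± 0.25 and PIK3CD at -0.35 ± 0.18. Toll-like receptor genes had 1 of 25 higher and 1 lower, the same adjusted over the list alone (adjusted p = 0.348): PELI1 at 0.31 ± 0.12 and TLR2 at -0.59 ± 0.22. Germinal centre genes had 2 higher and 1 lower of 16, the same adjusted over the list alone (adjusted p = 0.234). BACH2 lay at 0.46 ± 0.09, IRAG2 at 0.36 ± 0.12 and LMO2 at -0.67 ± 0.32. Immediate early genes had 2 higher and 3 lower of 24 (3 and 3 adjusted over the list alone; adjusted p = 0.945). DUSP1 lay at 0.57 ± 0.07, JUN at 0.54 ± 0.28, DUSP2 at -0.49 ± 0.19 and IER3 at -0.41 ± 0.18, and a median of -0.01 against a mean of 0.04 and a test that pointed up. Targets of p53 had 2 higher and 3 lower of 22 (4 and 3 adjusted over the list alone; adjusted p = 0.537). TP53INP1 lay at 0.69 ± 0.29, BTG2 at 0.47 ± 0.37, PLK3 at -0.47 ± 0.16 and PHLDA3 at -0.40 ± 0.21. DNA replication had 1 higher and 2 lower of 24 (2 and 3 adjusted over the list alone; adjusted p = 0.203). TYMS lay at 0.21 ± 0.05, MCM7 at -0.39 ± 0.28 and CDC6 at -0.21 ± 0.11. The unfolded protein response had 2 of 16 lower (2 higher and 2 lower adjusted over the list alone; adjusted p = 0.0898), HERPUD1 and XBP1 at -0.25 ± 0.14 each. Sterol synthesis had 2 of 19 lower (adjusted p = 0.374), INSIG1 at -0.30 ± 0.16 and NSDHL at -0.19 ± 0.10. Glycolysis and hypoxia had 2 of 20 higher (adjusted p = 0.626), ADM at 0.83 ± 0.36 and MXI1 at 0.18 ± 0.07, with a median of -0.05 against a mean of 0.0094. MHC class II had 2 of 12 higher (adjusted p = 0.651), HLA-DMB at 0.30 ± 0.22 and HLA-DOA at 0.30 ± 0.21, the latter at -0.06 as the mean over its probes. The G2/M list had 0 of 22 (adjusted p = 0.975). CENPF lay at 0.23 ± 0.20 and CDK1 at -0.22 ± 0.22, and a median and mean of 0.01 against a test that pointed down. Oxidative phosphorylation had 0 of 20 (adjusted p = 0.626). CYCS lay at 0.17 ± 0.17 and NDUFS3 at -0.13 ± 0.10. T and NK cell markers had 2 higher and 1 lower of 11 (4 and 1 adjusted over the list alone; adjusted p = 0.602). GZMA lay at 1.56 ± 0.37 though its Cy3 signal was above background on 0 of 8 scanner arrays, CD8B at 0.39 ± 0.32 and CD3G at -0.78 ± 0.73, and a median of -0.03 against a mean of 0.13. Myeloid markers had 2 of 10 higher (adjusted p = 0.501), ITGAM at 0.32 ± 0.13 and VCAN at 0.31 ± 0.25, and fibroblast markers had 0 of 9 (adjusted p = 0.651). COL5A1 lay at 0.29 ± 0.36 and COL3A1 at 0.19 ± 0.23. By fry the T and NK cell and the myeloid lists were higher (adjusted p = 0.0255 each), though neither passed camera.

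**Figure D3:**
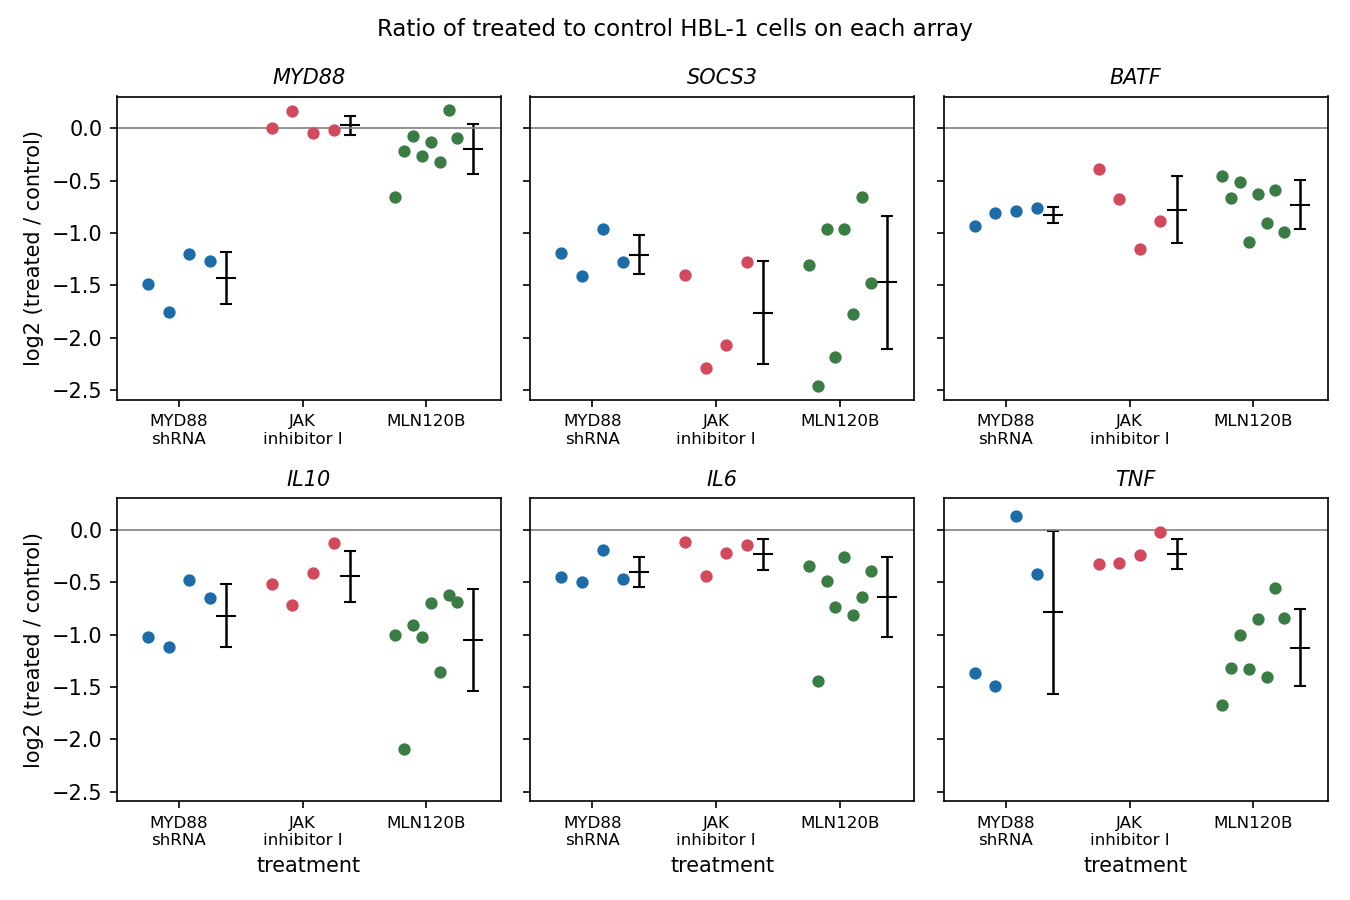
Log2 ratio of treated to control cells (y axis, log2, from the deposited ratios) of 6 genes on each array, by treatment (x axis); points are arrays in order of time, bars the mean ± SD over 4, 4 and 8 arrays. MYD88 lay at -1.43 ± 0.25 on the MYD88 shRNA arrays and near 0 (0.03 ± 0.09) on the JAK inhibitor arrays, while SOCS3, BATF, IL10 and IL6 lay below 0 on every array of the 3 treatments. Negative control spots lay below 0 on every array too, at means of -0.73 (MYD88 shRNA), -1.02 (JAK inhibitor I) and -0.47 (MLN120B). This limits what the sign shows for dim genes. IL6 under the JAK inhibitor lay at -0.23 here and at -0.09 from the scanner files.

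Differences between the treatments were tested on the deposited ratios of all 16 arrays, with values as the difference ± SE. A dye effect of a probe cancels there only where it is equal on all arrays, which was not tested for all genes. The MYD88 shRNA and MLN120B arrays address how far the responses to MYD88 loss and to IκB kinase beta inhibition differ. MYD88 itself was lower under its shRNAs by -1.23 ± 0.13 (adjusted p = 0.00168), and the amino acid transporter gene SLC16A10 (-1.10 ± 0.16), FBXO36 (-0.94 ± 0.15), the smooth muscle gene CNN1 (-0.94 ± 0.15) and APOLD1 (-0.55 ± 0.09) were lower too. KIF26B (1.09 ± 0.18) and PCDHGA12 (0.49 ± 0.08) were higher. Several of these differences rest largely on the MLN120B arrays. Means under the shRNAs and MLN120B were -0.75 and 0.35 (SLC16A10), -0.32 and 0.62 (FBXO36), -0.19 and 0.75 (CNN1) and 0.19 and 0.74 (APOLD1). For KIF26B they were -0.15 and -1.23, and for PCDHGA12 0.44 and -0.06. IL10 differed by 0.23 (adjusted p = 0.976) and IL6 by 0.24 (adjusted p = 0.94). In all, 10 of 23872 genes passed, 5 in each direction, and 1467 had an unadjusted p under 0.05. The count was 8 within the run that held both groups and 1 with the arrays of these groups alone. Leaving out 1 array gave 23 genes without MLN120B 16 h, 2 without either shMYD88-7 array or MLN120B 2 h, 5 and 3 without shMYD88-4 at 24 h and 48 h, 4 without MLN120B 4 h or 6 h, and 3 without MLN120B 8 h. The groups share only the time of 24 h. Their labelled RNA (1 µg against 2 µg) and control cells (uninduced against untreated) cannot be told apart from the treatment.

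The MYD88 shRNA and JAK inhibitor arrays differed in 66 genes, 45 higher and 21 lower under the shRNAs. SLITRK5 (-1.80 ± 0.34), PDGFRL (-1.65 ± 0.26), MYD88 (-1.46 ± 0.15, adjusted p = 0.00122), MYO7A (-1.44 ± 0.21) and the serine protease gene TMPRSS6 (-1.07 ± 0.18) were lower. The immediate early genes EGR2 (1.80 ± 0.30) and EGR3 (1.51 ± 0.22), the lymphocyte GTPase gene GIMAP1 (1.99 ± 0.34), ARHGAP20 (1.77 ± 0.25) and OR5I1 (1.59 ± 0.29) were higher. Cy3 was above background on 1 of 8 scanner arrays for OR5I1 and on 4 for SLITRK5, PDGFRL, GIMAP1 and ARHGAP20, so the sizes of these differences are not exact. IL10 differed by -0.38 (adjusted p = 0.588) and IL6 by -0.17 (adjusted p = 0.768). The count was 29 and 21 without shMYD88-7 at 24 h and 48 h, 17 and 3 without shMYD88-4 at 24 h and 48 h, and 148, 30, 17 and 34 without the JAK inhibitor at 2, 4, 6 and 8 h. It was 367 with the scanner files, and the slide, scan and run of the JAK inhibitor arrays cannot be told apart from the treatment. The same holds for time, as no time is shared (24 h and 48 h against 2 to 8 h), and for control cells (uninduced against DMSO).

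The JAK inhibitor and MLN120B arrays differed in 310 genes, 74 higher and 236 lower under the JAK inhibitor. TNFAIP2 (1.50 ± 0.31), KIF26B (1.57 ± 0.18), the Ras activator gene RASGRP1 (1.16 ± 0.24), SUMO1P1 (1.65 ± 0.26) and SCARF2 (1.11 ± 0.24) were higher, the first 3 of them among the lowest genes of the MLN120B arrays. GIMAP1 (-2.14 ± 0.29), ARHGAP20 (-1.88 ± 0.22), GABRA4 (-1.60 ± 0.35) and TPD52L3 (-1.59 ± 0.37) were lower. Cy3 was above background on 0 of 8 scanner arrays for GABRA4 and TPD52L3, 3 for SUMO1P1 and 4 for GIMAP1 and ARHGAP20, so the sizes of these differences are not exact. IL10 differed by 0.61 (adjusted p = 0.159) and IL6 by 0.41 (adjusted p = 0.203). At the matched times of 2, 4, 6 and 8 h, with time as a block, 1 gene passed. The JAK inhibitor arrays also differ from the MLN120B arrays in their run of IDs, labelled RNA (1 µg against 2 µg) and control cells (DMSO against untreated). None of these can be told apart from the treatment. The count was 771, 71, 66 and 111 without the JAK inhibitor at 2, 4, 6 and 8 h, 735 without MLN120B 16 h, and 177, 133 and 158 without MLN120B at 6, 8 and 12 h.

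Between the shRNAs, tested with time as a term, 54 of 23353 genes differed, 22 higher and 32 lower with shMYD88-4. MYD88 itself lay at -1.25 with shMYD88-4 and at -1.42 with shMYD88-7, a difference of 0.17 (adjusted p = 0.563). NTAQ1 (-0.77 ± 0.07), the phosphatase gene CDC25C (-0.65 ± 0.08), MNX1 (-0.57 ± 0.07) and PTMA (-0.57 ± 0.08) were lower with shMYD88-4. TAMALIN (0.71 ± 0.12), LMO2 (0.66 ± 0.10), SYPL1 (0.62 ± 0.08), CYBRD1 (0.58 ± 0.10) and the transcription factor gene KLF2 (0.56 ± 0.10) were higher, and IL10 (0.09, adjusted p = 0.823) and IL6 (0.14, adjusted p = 0.673) did not pass. With each shRNA on 2 arrays, 0 genes passed in limma on the deposited ratios and 0 in a fit over all 8 scanner arrays, and 1956 had an unadjusted p under 0.05 in the fit given here. That fit leaves almost no spread of a gene's own. Its SEs and p-values rest mostly on the spread of other genes (16.94 prior degrees of freedom in limma).

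Between 24 h and 48 h of MYD88 shRNA, tested with the shRNA as a term, 1452 genes differed, 749 higher and 703 lower at 48 h. CTH, the cystathionine gamma-lyase gene, lay near 0 at 24 h with both shRNAs (-0.02 and 0.03) and at -1.21 with shMYD88-7 and -2.79 with shMYD88-4 at 48 h, a difference of -2.01 ± 0.20 (SE, adjusted p = 1.41e-05). GRB10 (-1.70 ± 0.13) and 3 genes of the integrated stress response, CHAC1 (-1.63 ± 0.18), ATF3 (-1.53 ± 0.18) and VLDLR (-1.50 ± 0.15), were also lower at 48 h. TNF was higher at 48 h by 1.17 ± 0.09, from -1.33 to -0.38 with shMYD88-7 and from -1.21 to 0.17 with shMYD88-4, and RTL5 (0.99 ± 0.24), EGR3 (0.92 ± 0.08), SNORD14E (0.83 ± 0.09) and DUSP2 (0.82 ± 0.08) were higher too. MYD88 was higher at 48 h by 0.36 ± 0.08 (adjusted p = 0.00896), IL10 by 0.33 ± 0.07 (adjusted p = 0.00977), and IL6 by 0.13 (adjusted p = 0.384). As between the shRNAs, 0 genes passed on the deposited ratios and 0 in the fit over the 8 scanner arrays, and 4542 had an unadjusted p under 0.05 here. The SEs and p-values again rest mostly on the spread of other genes (16.94 prior degrees of freedom). They measure little of the gap between the shRNAs, such as that of CTH at 48 h.

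**Figure D4:**
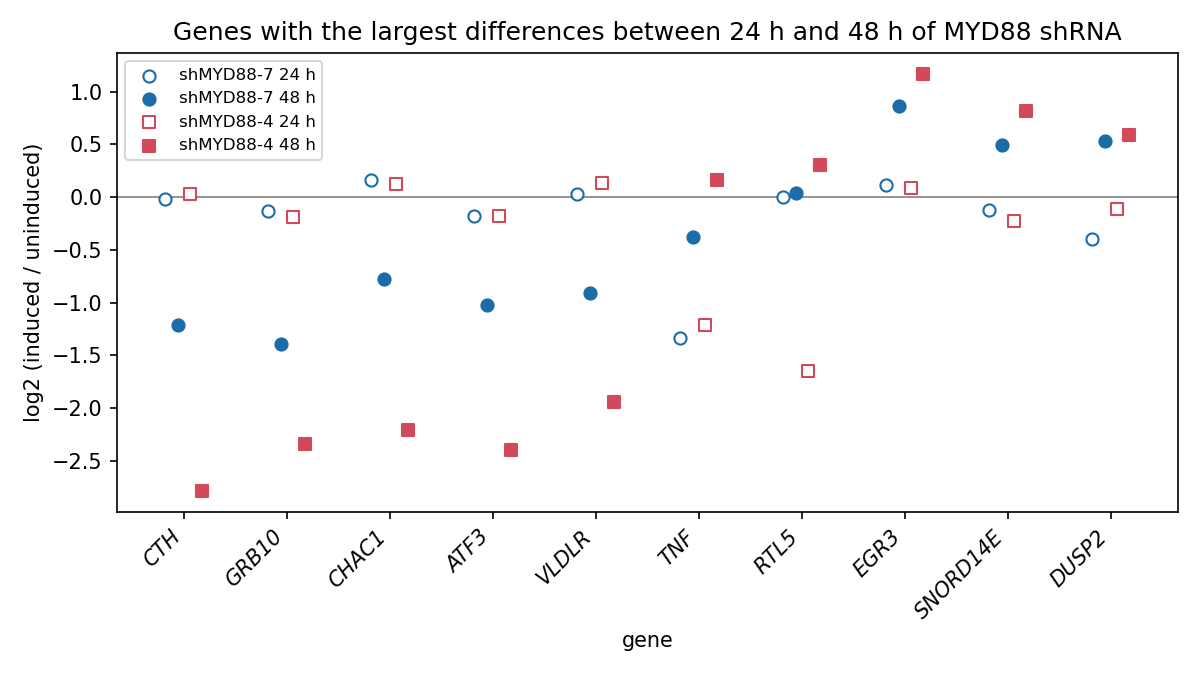
Log2 ratio of induced to uninduced cells (y axis, log2) of the 10 genes with the largest differences between 24 h and 48 h of MYD88 shRNA (x axis); each point is 1 array, open at 24 h and filled at 48 h, circles shMYD88-7 and squares shMYD88-4. CTH, GRB10, CHAC1, ATF3 and VLDLR lay between -0.19 and 0.16 on the 24 h arrays and between -2.79 and -0.78 on the 48 h arrays.

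Time slopes asked which responses grew or faded over the inhibitor courses. Under the JAK inhibitor IL10 had a slope of 0.18 per log2 hour, IL6 of -0.01 and MYD88 of -0.05, all with an adjusted p of 1, and 0 genes passed in limma, with 860 at an unadjusted p under 0.05 and 2 genes passing without the 4 h array. Under MLN120B IL10 had a slope of 0.19 (adjusted p = 0.676), IL6 of 0.07 (adjusted p = 0.826) and MYD88 of 0.12 (adjusted p = 0.671), and 0 genes passed in limma, with 1782 at an unadjusted p under 0.05 and a smallest adjusted p of 0.239; 1 gene passed without the 4 h array and 1 with hours in place of log2 hours.

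Genes lower under more than 1 treatment address which part of the MYD88 response is shared with IκB kinase beta or JAK inhibition; all values here are means of the deposited ratios. Each pair was fitted together with a shared spread, and the counts of lower genes differ from those of the single fits above (2426 for MYD88 shRNA, 15 for JAK inhibitor I and 1178 for MLN120B). A gene with a small spread passes more easily under both treatments, so the lists of a pair are not independent. The counts expected of independent lists and Fisher's p-values are therefore no measure of chance here, also with differences taken. Genes called in opposite directions numbered 2 and 1 for MYD88 shRNA and MLN120B and 7 and 1 for both inhibitors. For MYD88 shRNA and JAK inhibitor I they numbered 3 and 11. In these fits SOCS3 was lower under all 3, at -1.21 (MYD88 shRNA), -1.76 (JAK inhibitor I) and -1.47 (MLN120B), as were LRRC32 (-1.14, -1.28 and -1.96), ELF3 (-1.26, -1.61 and -1.36), GPRC5B (-1.27, -0.98 and -1.21) and ABTB2 (-1.14, -0.69 and -1.15), though none of these 5 passed in the JAK inhibitor fit above. Of 751 genes lower under MYD88 shRNA and 1976 lower under MLN120B, 541 were shared where independent lists would share 62.2 (odds ratio 38.9), and FCRL4, PDGFRL, S100A14, MYO7A and LILRB1 were among them. The MYD88 shRNA values were also taken as differences from the JAK inhibitor arrays, which cancels a dye effect that is equal on all arrays and removes what both share. There 14 genes were shared against 1.7 (Fisher's exact test, one-sided, p = 4.52e-11), PDGFRL and MYO7A included. MYD88 shRNA (1106 lower) and JAK inhibitor I (951 lower) shared 229 genes against 44.1 (Fisher's exact test, p = 2.52e-102), IL2RB, DEPP1, SYNM and the kinase gene SGK1 among them. JAK inhibitor I (307 lower) and MLN120B (1515 lower) shared 117 genes against 19.5 (Fisher's exact test, p = 2.11e-60), LMO2, ADAM18, DEPP1 and SGK1 among them. With the first group of the pair taken as its difference from the remaining treatment, which leaves few lower genes (5 and 45), MYD88 shRNA and JAK inhibitor I shared 0 against 0.2 and JAK inhibitor I and MLN120B 4 against 2.9 (Fisher's exact test, one-sided, p = 0.319). The full overlaps of these pairs therefore stand without a dye effect cancelled. Genes higher in both pairs with MYD88 shRNA numbered 653 against 109.2 (MLN120B) and 213 against 45.7 (JAK inhibitor I), and 127 against 19.7 were higher under both inhibitors. Across genes, which are not independent replicates, the mean ratios correlated at 0.675 (MYD88 shRNA and MLN120B), 0.388 (MYD88 shRNA and JAK inhibitor I) and 0.294 (JAK inhibitor I and MLN120B). Without MLN120B 16 h the shared lower genes of MYD88 shRNA and MLN120B numbered 1196, and without each MYD88 shRNA array 110 (shMYD88-4 48 h), 145 (shMYD88-4 24 h), 191 (shMYD88-7 48 h) and 205 (shMYD88-7 24 h). Those of MYD88 shRNA and JAK inhibitor I numbered 74, 52, 98 and 69 without the same arrays and 18 and 48 without JAK inhibitor I at 6 and 8 h. Those of both inhibitors numbered 16, 7 and 10 without JAK inhibitor I at 4, 6 and 8 h, 57, 56, 58 and 55 without MLN120B at 4, 6, 8 and 12 h, and 421 without MLN120B 16 h.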

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

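The tests on the corner control spots and on the highest MLN120B genes (dye effect, dim end and rise) were chosen only after the result was seen; the tests on ribosomal protein genes and other splits of the arrays were fixed before.

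By time, CTH was lower at 48 h than at 24 h of MYD88 shRNA by -2.01 log2, GRB10 by -1.70, CHAC1 by -1.635, ATF3 by -1.53 and VLDLR by -1.50. TNF was higher by 1.17, RTL5 by 0.99, EGR3 by 0.92, SNORD14E by 0.83 and DUSP2 by 0.82. RTL5 rested on the shMYD88-4 24 h array, at -1.65 against -0.0033 with shMYD88-7. In all 1452 genes differed between the times and 54 between the shRNAs in a fit on 4 arrays, but 0 and 0 on the value table and 0 and 0 in the fit over the 8 scanner arrays. With shMYD88-4 rather than shMYD88-7, NTAQ1 was lower by -0.77, CDC25C by -0.65, MNX1 by -0.57 and PTMA by -0.57, and TAMALIN was higher by 0.71, LMO2 by 0.66, SYPL1 by 0.62, CYBRD1 by 0.58 and KLF2 by 0.56.

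Between treatments, 66 genes differed between MYD88 shRNA and JAK inhibitor I, 310 between JAK inhibitor I and MLN120B and 10 between MYD88 shRNA and MLN120B. For the first, the real grouping was the 1 of 35 splits with as many genes and the highest other split gave 0. For the second, it was 1 of 100 splits drawn from the 495 possible, and the highest other gave 5. Both results argue against a chance split of these arrays, but go no further. The run of the JAK inhibitor arrays goes with the treatment in both, and the arrays of a group may not be separate cultures. At matched times with time as a block, 1 gene differed between the inhibitors. For the third, 2 of 100 splits, the real one included and again drawn from 495, gave as many genes. So few argue against a chance split. They cannot tie the 10 genes to the treatment, since the other split gave more. The other of these, with 34 genes, put the MLN120B arrays at 2, 4, 8 and 16 h against all arrays of the run with the MYD88 shRNAs. That split follows a run of sample IDs, which no label calls a technical run, and it separates time points and treatments as well. The correlation within runs that limma estimated for this difference was -0.0107, and what set the split apart was not tested. Within the run that holds both treatments the count was 8.

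The 10 genes highest under the JAK inhibitor, SPPL2B, PRR7, SOX3 and HRK among them, moved together on all arrays. Over the 8 MLN120B arrays, which did not choose them, their mean followed the corner control spots (r = 0.953, exact permutation p = 0.000372), single genes at 0.916 to 0.991, and so did 29 of the 40 higher calls and 0 of the 15 lower calls at r above 0.7, against 3.1% of all tested genes. The test of a rise under the JAK inhibitor beyond the corner spots did not show one, but cannot decide. The JAK inhibitor arrays lay -0.22 log2 on average from the line through the other 12 arrays (residual SD 0.21), or 0.12 without the 4 h array. The 4 h array alone lay at -1.24 from the line, which was extended there beyond the highest corner value of the other 12 arrays (0.60). Over the JAK inhibitor arrays the corner spots ran from 0.42 to 1.80 and the mean of the genes only from 0.76 to 0.93. A signal shared with the control spots is a candidate explanation for most higher calls, and a rise under the JAK inhibitor stays open beside it. Corner spots reached 1.80 on the JAK inhibitor 4 h array and -1.04 on the MLN120B 2 h array, and what made them vary was not tested.

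Ribosomal protein genes led the rises under the MYD88 shRNAs: 65 of 69 rose and 0 fell, with a median of 0.65, or 0.29 on the processed signals and 1.29 with median centring. An effect of processing at the bright end fits, since 59 other genes as bright had 0.799 of the median of the brightest 52 ribosomal protein genes. A rise of these transcripts fits as well: in the value table their median was 0.11 higher than on the MLN120B arrays of the same run (exact permutation p = 0.0286, the smallest that 4 against 4 allows), though the excess over the other bright genes was 0.04 (exact permutation p = 0.0857). Against all MLN120B arrays that excess was 0.11 (exact permutation p = 0.166), and against the JAK inhibitor arrays, whose slide and run differ as well, 0.09 (exact permutation p = 0.0286). Both explanations stay open.

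The 10 genes highest under MLN120B, OR2W3, TPD52L3 and GIMAP1 among them, lay above 0 on 8 of the 8 other arrays and were dim, with Cy3 above background on a mean of 0.5 of the 8 scanner arrays. Their mean was lower by -1.38 on the JAK inhibitor than on the MLN120B arrays (exact permutation p = 0.00202), with 5 of the 10 past the test, and by -0.41 on the MYD88 shRNA arrays (exact permutation p = 0.0545), with 0 past the test. Their median difference between the JAK inhibitor and MLN120B arrays was -1.43 (SD 0.55 over genes), against -0.55 for the negative control spots. A dye effect of the probes, a lower dim end of the ratio on the JAK inhibitor arrays and a rise under MLN120B cannot be told apart for these genes, since ratios this near the background are not exact and the genes were picked for their MLN120B ratios.

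Single arrays stood far from the others of their group in 31 of 337 groups of values (20 of 241 for named genes, 8 of 69 for lists, 3 of 27 for quality measures), where chance gives about 1 in 20; 12 were on MLN120B 16 h and 6 on shMYD88-4 48 h. On MLN120B 16 h the outlying values were MCM7 0.22, CEBPG -0.85, PLK3 -0.10, IER3 -0.79, CYCS -0.21 and COL5A1 1.14, the mean of the lists of B cell receptor genes 0.41, ABC lymphoma genes 0.19, DNA replication 0.18, immediate early genes 0.27 and oxidative phosphorylation -0.22, and the spike-in control probes 1.81, where the other MLN120B arrays had -0.78 to 0.41. On shMYD88-4 48 h they were BCL3 -0.23, IFIT1 -0.30, ATF5 -1.11, TP53INP1 0.57, IL6 -0.15 and 77.8% of probes above background in Cy5. Others were ADAM8 -1.17 and NPM1 0.75 on shMYD88-7 48 h, KIF11 -0.13 on shMYD88-7 24 h, and CCL4 -0.83 on shMYD88-4 24 h. Under the JAK inhibitor they were SPPL2B 1.46, CD4 0.46 and the apoptosis list -0.18 at 4 h, and 67% of probes above background in Cy3 at 2 h. Under MLN120B they were also IL6 -1.44 at 3 h, ITGAM 0.62 at 12 h, the G2/M list -0.16 at 24 h and the apoptosis list -0.35 at 2 h. Spike-in probes, which no comparison used, had a group mean of 0.64 ± 0.13 under the JAK inhibitor, -0.07 ± 0.19 under the MYD88 shRNAs and 0.11 ± 0.77 under MLN120B.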

How the results depend on the processing

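Tests without the JAK inhibitor I 4 h and MLN120B 16 h arrays, on the value table for lists and on single runs for lists were chosen only after the results were seen. Where a count moved by over 1.5 times, the cause was not tested.

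MYD88 shRNA gave 5805 genes, and 5260 to 5824 without background correction or filter, with both channels above background, an intensity trend or the mean over probes. It gave 3393 on the processed signals, 3396 on the value table, 18321 with median centring (12464 higher, 5857 lower), 3112 with the spread shared with the JAK inhibitor arrays, 9116 with shRNA and time as terms and 161 with a minimum change of 1.5-fold. JAK inhibitor I gave 55 genes, and 54 to 72 on the processed signals, the value table, with both channels, a trend or no filter. It gave 27 without background correction, 4717 with median centring (4376 higher, 341 lower), 2502 with the shared spread, 0 with log2 time as a term, 0 with the mean over probes and 36 with the minimum. MLN120B gave 3198 genes, and 2782 to 4036 with loess, median centring, both channels, log2 time or the mean over probes. It gave 5019 with the run as a random block, 57 in the run of 2, 4, 8 and 16 h, 909 in the run of 3, 6, 12 and 24 h, 570 at 2, 4, 6 and 8 h alone, 5131 with a spread shared by 16 arrays, 7337 without a filter (2421 higher, 4916 lower) and 461 with the minimum.

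The differences between MYD88 shRNA and MLN120B (10) kept to 8 to 11 with no filter, a random block, median centring or within the shared run, with 1 on these groups alone and 22 without the JAK inhibitor I 4 h and MLN120B 16 h arrays, the pair left out below. MYD88 shRNA minus JAK inhibitor I (66) gave 61 with median centring, 182 without a filter, 108 with a random block, 34 on these groups alone, 367 from the scanner files and 226 without the pair. JAK inhibitor I minus MLN120B (310) gave 278 to 359 with no filter, a random block, median centring or without the pair, 79 on these groups alone and 1 at matched times with time as a block. The shRNA difference (54) gave 0 in the fit over 8 arrays, 123 with median centring, 184 without a filter and 0 on the value table. The time difference (1452) gave 0 in the fit over 8 arrays, 749 with median centring, 1713 without a filter and 0 on the value table. Slopes stayed at 0 in every setting but hours for MLN120B (1) and left-out arrays.

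Lists past camera numbered 11, 9 and 8 for MYD88 shRNA, JAK inhibitor I and MLN120B. They numbered 0, 0 and 0 with an estimated correlation, 8, 3 and 7 by fry, 13, 9 and 4 without a filter, and 10, 11 and 8 with median centring, where 7 of the 10 and all 11 pointed up. On the value table they numbered 11 and 9, and 4 and 8 in the MLN120B runs of 2, 4, 8, 16 h and of 3, 6, 12, 24 h. Shared lower genes were 541 (MYD88 shRNA and MLN120B), 229 (MYD88 shRNA and JAK inhibitor I) and 117 (both inhibitors). They were 40, 23 and 13 with the minimum, 14, 0 and 4 with the first group as its difference from the treatment not in the pair, which also removes what those share and left 21, 5 and 45 lower genes to overlap, 3473, 2221 and 2443 without a filter, and 1196, 214 and 193 without the pair.

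Leaving out each array in turn gave 2905 to 4488 genes for MYD88 shRNA, 0 to 565 for JAK inhibitor I and 1695 to 5657 for MLN120B. Differences ran from 2 to 23 (MYD88 shRNA minus MLN120B), 3 to 148 (minus JAK inhibitor I) and 66 to 771 (JAK inhibitor I minus MLN120B), and slopes from 0 to 2 (JAK inhibitor I) and 0 to 1 (MLN120B). Lists ran from 10 to 13 (MYD88 shRNA), 8 to 8 (JAK inhibitor I) and 7 to 9 (MLN120B). Shared genes, in the order above, ran from 110 to 1196, 18 to 262 and 7 to 421.

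Of the values of named genes under the alternatives, 3702 kept their side of the threshold, 737 no longer passed, 74 newly passed, and 23 changed sign where either value passed. Under median centring, MYD88 shRNA values included PDIA4 0.16, UBE2C 0.17, CDK1 0.13, PLK1 0.26, KIF11 0.0844, CDC45 0.12, NIP7 0.036, MRTO4 0.0492, ASNS 0.10, INSIG1 0.0538, MVD 0.0128, DHCR7 0.19, LDHA 0.29, HK2 0.12, PFKFB4 9e-04, GZMA -0.24 and CD68 -0.0073, and JAK inhibitor values IER2 0.16 and ATP5F1B 0.49. MANF under MYD88 shRNA was -0.0186 on the processed signals and -0.0191 on the value table, and HLA-DOA under MLN120B -0.0579 with the mean over probes. A Cy3 signal of 1.62 to 1.9 times background limits ratios of dim genes, and for the MLN120B arrays that limit was not analysed here.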

Other observations

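The list tests of differences between treatments, which cancel a dye effect of the probes where it is equal on all arrays, were chosen only after the results were seen.

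Averaged over all times, MHC class II genes, which present antigen to T cells, were higher under the MYD88 shRNAs than under either inhibitor. The median difference of the list was 0.30 from MLN120B (camera adjusted p = 3.67e-11; adjusted p = 0.133 with an estimated correlation) and 0.35 from JAK inhibitor I (adjusted p = 5.56e-07; adjusted p = 0.224 with an estimated correlation). DNA replication genes were lower under the shRNAs, by a median of -0.18 from MLN120B (adjusted p = 8.51e-10; adjusted p = 0.0999 with an estimated correlation) and -0.10 from the JAK inhibitor (adjusted p = 0.00496; adjusted p = 0.419 with an estimated correlation). The integrated stress response was lower, averaged over all times, by -0.40 from MLN120B (adjusted p = 8.7e-10; adjusted p = 0.371 with an estimated correlation) and -0.28 from the JAK inhibitor (adjusted p = 0.0028; adjusted p = 0.855 with an estimated correlation). None of these passed with an estimated correlation. At 24 h, the time that the shRNAs share with MLN120B, the mean of the MHC class II list was 0.20 (shMYD88-7), 0.21 (shMYD88-4) and 0.21 (MLN120B), against 0.37 and 0.59 with the shRNAs at 48 h. That of the stress response was -0.08 with both shRNAs at 24 h, above MLN120B at 24 h (-0.63) and above the JAK inhibitor arrays (-0.44 to -0.19), and -0.64 and -1.37 with the shRNAs at 48 h. The MHC class II difference from MLN120B was therefore not seen at 24 h. It rests on the 48 h shRNA arrays and on the earlier MLN120B arrays, where the list mean was -0.06 to 0.16. The stress response difference rests on the 48 h arrays, against MLN120B and the JAK inhibitor alike. That of DNA replication was -0.15 and -0.26 with the shRNAs and -0.15 under MLN120B at 24 h.

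Averaged over all times, NF-κB targets lay 0.14 higher under the MYD88 shRNAs than under MLN120B (adjusted p = 0.00372; adjusted p = 0.433 with an estimated correlation). They differed by -0.16 between the shRNAs and the JAK inhibitor (adjusted p = 0.00269; adjusted p = 0.419 with an estimated correlation) and lay 0.22 higher under the JAK inhibitor than under MLN120B (adjusted p = 9.08e-07; adjusted p = 0.188 with an estimated correlation). Type I interferon genes differed by -0.26 between the shRNAs and the JAK inhibitor (adjusted p = 1.87e-07; adjusted p = 0.371 with an estimated correlation) and by 0.18 between the JAK inhibitor and MLN120B (adjusted p = 0.000291; adjusted p = 0.559 with an estimated correlation). Cytokines and chemokines differed in the same pairs by -0.23 (adjusted p = 0.00269; adjusted p = 0.188 with an estimated correlation) and 0.31 (adjusted p = 0.00132; adjusted p = 0.188 with an estimated correlation). Immediate early genes lay 0.31 higher under the shRNAs than under the JAK inhibitor (adjusted p = 0.000109; adjusted p = 0.188 with an estimated correlation) and differed by -0.27 between the JAK inhibitor and MLN120B (adjusted p = 0.00441; adjusted p = 0.367 with an estimated correlation). At 24 h the mean of the NF-κB list was -0.42 and -0.39 with the shRNAs and -0.41 under MLN120B, so that difference was not seen at the shared time. At 2 h the interferon and cytokine lists differed the other way between the inhibitors, at -7e-04 and -0.21 under the JAK inhibitor and 0.05 and -0.20 under MLN120B.

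A further MYD88 probe, A_23_P92140, had a mean ratio in the value table of -1.61 ± 0.27 (SD, n = 4) on the MYD88 shRNA arrays, -0.16 ± 0.32 (n = 4) on the JAK inhibitor arrays and -0.34 ± 0.52 (n = 8) on the MLN120B arrays. From the scanner files it was -0.94 ± 0.17 (n = 4) on the MYD88 shRNA arrays and -0.05 ± 0.21 (n = 4) on the JAK inhibitor arrays. Across all probes, arrays of a group correlated at 0.207 to 0.623 (JAK inhibitor I) and 0.087 to 0.576 (MLN120B), with a median of 0.524 for MYD88 shRNA. The lowest correlation, -0.242, was between JAK inhibitor I 4 h and MLN120B 16 h.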
